A study of Mus musculus with 2 samples.

How the data were processed

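DNase-seq was done on postnatal hindbrain of B6NCrl mice at day 0, with both sexes pooled, in 2 biological replicates that form 1 group. Per the labels the replicates are different tissue samples recorded under the same donor entry, and how many animals each holds is not given in the sources used here. No test treats the replicates as a sample of animals: intervals and p-values are over peaks, genes or regions of these libraries. Read depth per library is unknown, since the tables used here hold regions and no read counts.

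Per the labels and the authors' file list, peaks and hotspots were called for each library separately from its filtered alignments on mm10, and the replicates were not pooled. The caller, its version, its threshold and the aligner are not given in the sources used here. In the authors' deposited peak tables the value per peak is a score, a whole number from 1 to 150, whose meaning and scaling are not stated; the p and q fields are empty. Nearly every peak is 150 bp wide. The score was used only to rank, describe or filter peaks within a list. In the deposited hotspot tables the value is a −log10 q, from 1.30 to a cap of 100 that 34.8% and 34.0% of hotspots of replicates 1 and 2 reach. All peaks lay in a hotspot of their own library, and every hotspot held a peak (100% in both). Exact duplicate peaks, 31 and 39, were kept in counts. Peaks on the mitochondrial chromosome and on unplaced scaffolds were left out of all comparisons, which left 270757 and 171790 peaks.

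Peaks of the replicates were taken as shared when they overlapped by at least 1 bp. Shared regions are the union of both lists, merged at 1 bp, where both have a peak. Chance overlap came from 100 circular shifts within each chromosome. Rank agreement is Spearman's rho over pairs chosen by best overlap. Location followed the order promoter (within 500 bp of the start site of any annotated transcript), exon, intron, intergenic, in an annotation of the same genome build as the peaks. A gene had a promoter peak in both replicates when a peak of each lay in any of its start site windows; the peaks need not overlap each other. Distal regions lie over 500 bp from every start site and were assigned to the nearest protein-coding start site; the stretch of genome nearest to a gene is its territory.

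Gene lists, the tests of the main comparisons, thresholds, named-gene rule and all alternatives except those said to be added were set before the data were examined. The 25 lists were Hox paralogue groups 1 to 8 and 9 to 13, cerebellar granule cell lineage, Purkinje cell, inhibitory interneuron lineage, brainstem nuclei, pan-neuronal, radial glia and astrocyte, oligodendrocyte lineage, microglia, endothelial and mural, meningeal and fibroblast, choroid plexus and ependyma, neural crest and Schwann, erythroid, lymphoid, forebrain, liver, skeletal muscle, heart, axon guidance, synapse and neurotransmitter receptors, Sonic hedgehog pathway, cell cycle, and housekeeping. They were set from textbook knowledge, and 472 of 473 entries matched the annotation (Ahsp did not). Some genes stand in more than 1 list, such as Egr2, Mycn, Gad1, Sox10, Ttr and Hoxb1, so the lists are not independent. Named genes are up to 4 members of each list with a promoter peak in both replicates and the highest mean percentile of score, up to 4 members with none in either (alphabetical), the 10 genes with the most distal regions, those nearest the 10 highest-ranked regions, and all Hox genes; a few genes, loci and motifs that these rules would name are not reported here, and others are named with the statement that they were chosen after their values were seen. The members with the most regions in each list past the distal threshold (Mbp and Bcas1 at the same number, Myt1l, Robo1, Sox9 and Meis1) were chosen after their values were seen; of the tied genes, only Mbp was left out in the alternative without the top member.

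Promoter lists were tested with a two-sided Fisher's exact test against all other protein-coding genes, and distal lists by permutation against 10000 random lists of the same size matched on the decile of territory length, each with Benjamini-Hochberg adjustment over the 25 lists and a threshold of 0.05. Motifs were 34 textbook consensus sequences, searched on both strands of 200 bp around the centre of each distal region and of a flank 1000 bp away outside hotspots; 102666 of 107430 distal regions had such a flank. An exact binomial test was run on regions where only the region or only its flank matched. The alternative with GC-matched windows used a chi-square test of the matching shares, with no requirement on each replicate. Alternatives were the stronger part of each list (scores at or above its median), a reciprocal overlap of 50%, hotspots in place of peaks, lists of equal length, autosomes only, promoter windows of 1000 bp, only the 5′ end of a gene, random lists matched on promoter CpG content, regions in the gene body or within 50000 bp, GC-matched windows, flanks 2000 bp away, and each replicate left out. Added after seeing the data were distal lists without their top member, neighbouring members within 200000 bp counted once, and a background without the olfactory, vomeronasal and keratin-associated families.

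The overlap, rank, location, list, missing-share, scan and flank motif steps were tested on simulated data; the comparison of motifs with GC-matched windows was not. Overlap, shared regions and promoter assignment returned what the simulation was made with (59.3% of 20000 peaks, 11869 regions, 2194 of 2194 genes), and Spearman's rho was 0.912 for a made value of 0.910. All 500 of 500 regions got the location class found by a separate search. Of 600 promoter lists planted at other shares 79.0% were called, and of 1900 unplanted lists 0.684%. Against lists matched on CpG content 97.0% of 100 planted and 0% of 400 unplanted lists were called. For distal lists the power was low and depended on the simulated spread. With the real counts shuffled among genes of a territory decile, 37.0% of 100 lists planted at a ratio of 2 and 1.00% of 400 unplanted lists were called; with negative binomial counts of wide spread, 4.00% and 0.500% were called. A distal list that missed the threshold may therefore still differ. For the share of missing distal peaks, 56.0% of 100 lists planted at a ratio of 2 and 0.500% of 400 unplanted lists were called, and given the score, 10 of 10 planted and 0 of 40 unplanted sets lay above all shuffles. The scans found 18 of 20 planted windows and 20 of 20 planted runs, and 0 of 6365 unplanted windows. The simulations of the score test and the scans drew unplanted missing peaks independently within score deciles, as the shuffles do. Missing peaks in the data cluster, so these simulations do not give the error rate of those tests in the data. All 6 planted motifs were called, and 1 unplanted motif was, in 20000 random windows; this simulation did not apply the requirement on each replicate. Tools were Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.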

Results

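DNase-seq maps open chromatin: DNase I cuts DNA where it is not wrapped in nucleosomes or otherwise shielded, and the released ends are sequenced. Hindbrain, the part of the brain that holds the cerebellum, pons and medulla, was taken from B6NCrl mice at postnatal day 0, with males and females pooled. The series holds 1 group with 2 biological replicates and no second condition, so the comparisons are between the replicates and between the regions found in both and the mouse gene annotation. Replicate 1 had 271150 peaks and replicate 2 had 172002, a ratio of 1.58, and the broader hotspots numbered 240650 and 151801. Peaks covered 39.99 Mb and 25.2 Mb, and hotspots 78.3 Mb and 55.2 Mb. Read depth is unknown, so the precision behind a single peak cannot be given, and intervals on shares cover counting error only.

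The first question was how far the replicates found the same open regions. Peaks at strong sites recurred, and those at weak sites often did not. Of the peaks of replicate 1, 51.6% overlapped a peak of replicate 2 by at least 1 bp (exact binomial 95% interval 51.4 to 51.8), and of the peaks of replicate 2, 82.5% overlapped a peak of replicate 1 (82.3 to 82.7). Randomly shifted peak lists gave 1.94% ± 0.0411 and 3.10% ± 0.0637 (SD, n = 100 shifts). In the highest decile of the authors' peak score 97.3% of replicate 1 peaks and 99.3% of replicate 2 peaks were found in the other replicate, against 9.98% and 38.7% in the lowest decile. Merging the lists gave 136714 regions with a peak of each replicate, covering 24.6 Mb with a median width of 170 bp. With the lists of equal length, recovery was 70.97% of replicate 1 and 72.2% of replicate 2.

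**Figure D1:**
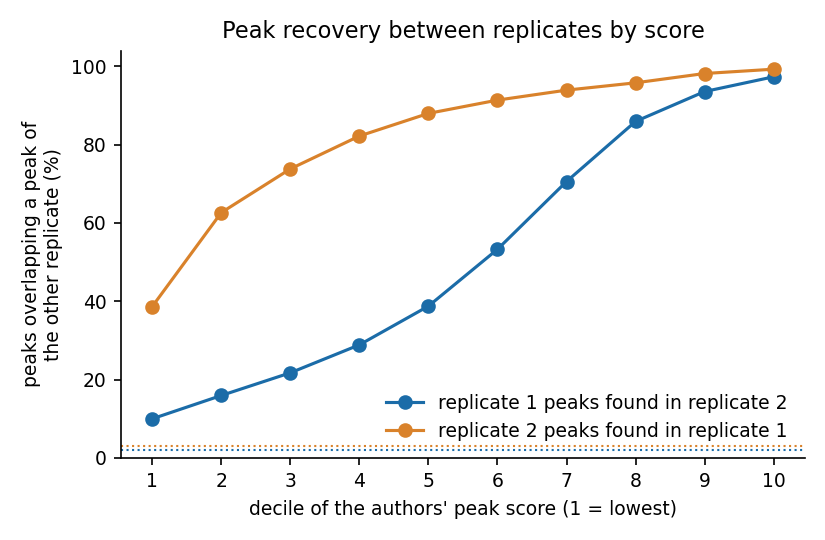
Share of peaks that overlap a peak of the other replicate (%, vertical axis) by decile of the authors' peak score within each list (horizontal axis, 1 is the lowest), with dotted lines for randomly shifted lists. Recovery rises with the score in both directions, to 97.3% for replicate 1 and 99.3% for replicate 2 in the highest decile.

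The order of peak strength was similar in the replicates. Across 137842 pairs of overlapping peaks, Spearman's rho of the authors' score was 0.912; peaks are not independent replicates, so no p is given. The score had a median of 65 in replicate 1 and 44 in replicate 2 at these pairs and was higher in replicate 1 at 96.1% of them, and since its scaling is not given this does not measure a change in accessibility. The 130967 peaks found in replicate 1 only had a median score of 34, against 64 for its shared peaks. The 30024 peaks found in replicate 2 only had a median of 25, against 43. Promoters held 10.2% of the peaks unique to replicate 1 and 16.2% of those unique to replicate 2, while about equal shares of the shared peaks, 21.11% and 21.02%, lay there.

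The second question was where in the genome the open regions lay. Promoters were the location most in excess of chance: 21.4% of the 136714 regions (exact binomial 95% interval 21.2 to 21.6) lay within 500 bp of an annotated transcription start site, 5.57 times the 3.85% of shifted regions. Introns held 38.4%, close to the shifted 39.3%, exons 6.05% against 4.93%, and intergenic DNA 34.1% against 51.9%. Promoter peaks also had the highest scores, with medians of 76 and 62 in replicates 1 and 2 against 40 and 35 for intergenic peaks. The 10 highest-ranked regions were all at promoters. The highest lay 2 bp from a start site of Hjurp, a chaperone that loads the centromeric histone, at chromosome 1, 88277556 to 88277705 (mm10), with scores of 150 and 147. The next lay at Fam76a, Fam76b and Rnf44, then at Eif4g2, a translation initiation factor, Acin1, Fxr2, a relative of the fragile X protein, Stt3b, a subunit of the enzyme that attaches sugar chains to proteins, 1810013L24Rik and the splicing factor Sf1. The share at promoters depends on the definition: it was 15.6% with only the 5′ end of each gene and 27.2% with 1000 bp on each side.

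The next question was which genes had an open promoter in both replicates. Of 21938 protein-coding genes, 14541 (66.3%, exact binomial 95% interval 65.7 to 66.9) had a promoter peak of each replicate. A further 984 had 1 in replicate 1 only, 109 in replicate 2 only, and 6304 in neither; shifted regions gave 12.1% ± 0.342 (SD, n = 100 shifts). The share rose with the CpG content of the promoter, here and below measured within 500 bp of the gene's 5′ end only, from 8.84% in the lowest decile to 98.2% in the highest. Gene families that are silent in most of the brain were low: 30 of 1135 olfactory receptor genes, 9 of 331 vomeronasal receptor genes and 4 of 57 keratin-associated protein genes had a promoter peak in both. In replicate 1 alone the numbers were 71, 15 and 13, and in replicate 2 alone 40, 12 and 4. Promoter windows of 3200 genes touch a window of another gene, and a peak there counts for both. A gene without a promoter peak was below the authors' calling threshold in these libraries, which does not show closed chromatin.

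The pan-neuronal, radial glia and astrocyte, granule cell and inhibitory interneuron lists had promoter peaks more often than other genes. All 20 pan-neuronal genes had a promoter peak in both replicates, among them the neuronal tubulin Tubb3 (scores 143 and 123 in replicates 1 and 2), the microtubule protein Map2 (143 and 117) and the vesicle fusion protein Snap25 (133 and 121). All 20 radial glia and astrocyte genes did so too, led by Id4 (146 and 135), Nfia (142 and 123), Sox9 (140 and 118) and the Notch target Hes5 (133 and 106). In the list for cerebellar granule cells, the neurons that fill the inner layer of the cerebellar cortex and arise largely after birth, 24 of 25 genes had one, including the synapse organiser Cbln1 (142 and 126), Sema6a (140 and 123), the transcription factor Zic1 (136 and 121) and Mycn (132 and 114). The same held for 14 of 15 genes of the inhibitory interneuron lineage list, with Sall3, Tfap2a, Gbx2 and Tlx3 the highest. The name of this list does not show that each member marks inhibitory cells.

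The axon guidance, synapse, Sonic hedgehog, cell cycle and housekeeping lists were also higher than other genes. Promoter peaks in both replicates were found at 24 of 25 axon guidance genes, with Plxna2, the netrin receptor Dcc, Unc5b and Unc5c the highest, and at 24 of 25 synapse and receptor genes, with the scaffold Dlg4 (137 and 127), the inhibitory synapse scaffold Gphn (142 and 119), Homer1 and Nlgn2. All 16 genes of the Sonic hedgehog pathway, which drives granule cell precursors to divide, had one, led by Sufu (139 and 132), Gas1, Mycn and Gli2. So did all 21 cell cycle genes, with the replication helicase gene Mcm4 (146 and 137), the mitotic kinase gene Cdk1, Mcm7 and Mcm5 highest, and all 18 housekeeping genes, with Rpl13a, Polr2a, Actb and Eef1a1 highest. These 9 lists were higher than all other protein-coding genes by a two-sided Fisher's exact test, with adjusted p from 0.00217 for cell cycle to 0.0427 for inhibitory interneurons (Benjamini-Hochberg over 25 lists). The test counts genes, not replicates, and says that a list stands apart in these libraries. Against random lists matched on promoter CpG content the pan-neuronal (adjusted permutation p = 0.00643), radial glia and astrocyte (0.00583), granule cell (0.0300) and synapse (0.00125) lists stayed past the threshold, and the inhibitory interneuron (1), axon guidance (0.238), Sonic hedgehog (0.0858), cell cycle (0.850) and housekeeping (0.108) lists did not. The Sonic hedgehog, cell cycle and housekeeping lists already had a promoter peak at every member, so the matched test could not have called them higher. With only the 5′ end of each gene the inhibitory interneuron (80%, adjusted p = 0.221), glial (85%, 0.0607) and synapse lists (80%, 0.0931) did not pass Fisher's exact test, and the interneuron list also missed with windows of 1000 bp (adjusted p = 0.0803) and without the receptor and keratin-associated families among the other genes (0.109).

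**Figure D2:**
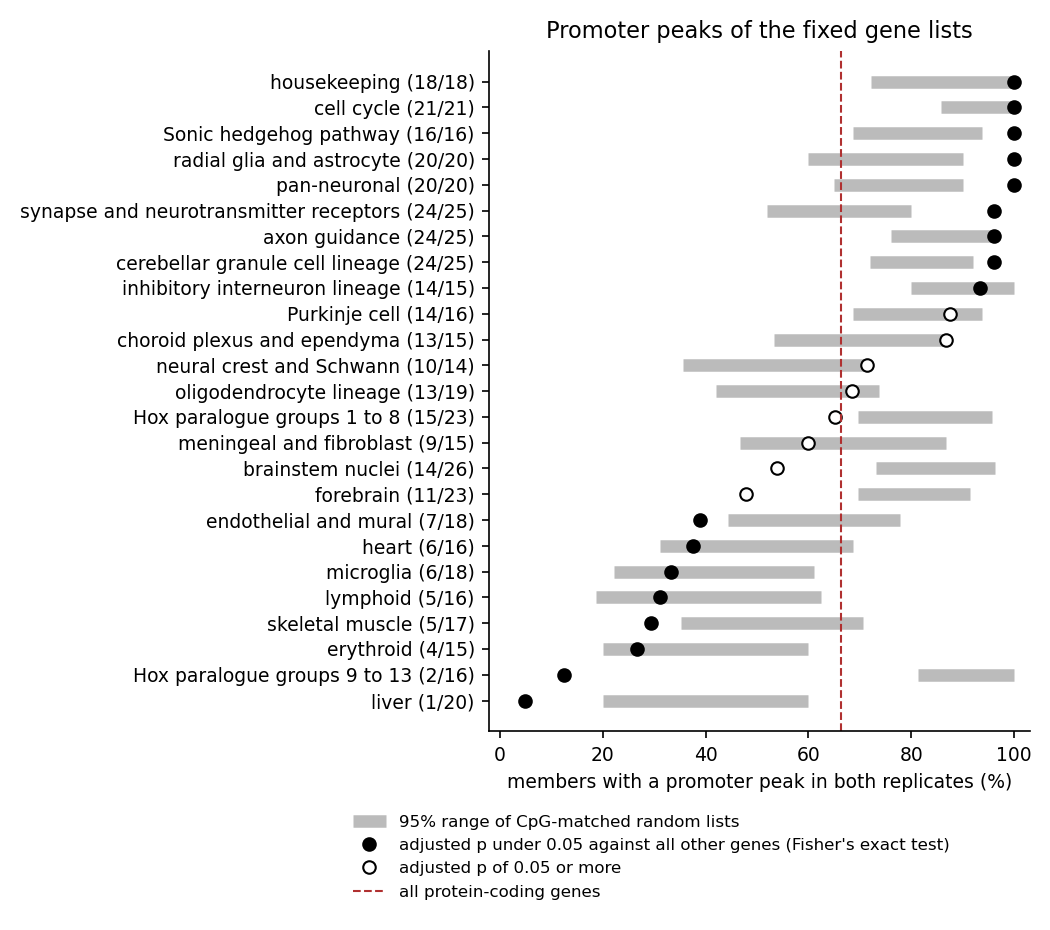
Share of each gene list with a promoter peak in both replicates (%, horizontal axis; members with a peak over members in brackets). Filled circles passed an adjusted p of 0.05 by Fisher's exact test against all other genes, open circles did not, grey bars span 95% of random lists matched on promoter CpG content, and the dashed line marks all protein-coding genes at 66.3%. Both Hox lists and the brainstem, forebrain, endothelial, liver and skeletal muscle lists lie below their bars, and the granule cell, pan-neuronal, glial, synapse and Sonic hedgehog lists above.

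Promoters of the liver, muscle, heart, lymphoid and erythroid lists had peaks less often than those of other genes. The liver list was the lowest, with 1 of 20 genes, the fetal serum protein gene Afp (scores 85 and 63), and no promoter peak in either replicate at Alb, Apoa1, Apoa2 or Ahsg. Skeletal muscle had 5 of 17, among them Mylpf (137 and 128) and Myh8 (96 and 64), with none at Ckm, Acta1, Myf5 or Myf6. Heart had 6 of 16, among them Ryr2 (125 and 84) and Tnni3 (90 and 69), with none at Gata4, Hand1, Hand2 or Myh6. Lymphoid genes had 5 of 16, among them Lck (127 and 107) and Pax5 (127 and 90), with none at Cd3e, Cd3g or Cd4. Erythroid genes had 4 of 15, namely Ank1, Tal1, Epor and Nfe2, with none at Gata1, Alas2 or the alpha-globin genes Hba-a1 and Hba-a2.

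The microglial list and the endothelial and mural list were also low. Microglia, the resident macrophages, had 6 of 18, with Irf8 (125 and 100), Sall1 and Cd68 among them and no promoter peak at Aif1, Cx3cr1, Fcer1g or Itgam. Endothelial and mural genes had 7 of 18, with the glucose transporter gene Slc2a1 (129 and 113), Kdr, Flt1 and Rgs5 the highest and none at Pecam1, Erg, Emcn or Foxq1. Together with Hox paralogue groups 9 to 13, described below, these were the 8 lists lower than other genes by two-sided Fisher's exact test, with adjusted p from 3.58e-07 for liver to 0.0441 for heart. A list states how many of its promoters were open and not how many cells of a type were present. Against CpG-matched lists only liver (adjusted permutation p = 0.00583) and Hox groups 9 to 13 (0.00125) stayed lower. In replicate 1 alone promoter peaks were found at 13 of 18 endothelial (72.2%), 11 of 18 microglial (61.1%) and 9 of 17 muscle genes (52.9%), which ended those calls, and at 3 of 20 liver genes (15%) and 7 of 16 genes of Hox groups 9 to 13 (43.8%), which did not; endothelial (44.4%), muscle and heart lists (56.2%) also missed the threshold with windows of 1000 bp, the endothelial list with only the 5′ end of each gene, and the muscle list with hotspots. Among the stronger peaks the shares fell to 12.5% for heart, 22.2% for endothelial genes and 6.25% for Hox groups 9 to 13, and with only the 5′ end to 13.3% for erythroid, 6.25% for lymphoid and 17.6% for muscle genes; liver rose to 10% with hotspots and 15% with windows of 1000 bp and was still called.

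The other 8 lists did not pass the threshold. Purkinje cells, the output neurons of the cerebellar cortex, had 14 of 16 genes (Fisher's exact test, adjusted p = 0.137), led by the calcium release channel gene Itpr1 (137 and 123), Lhx1 (127 and 108), Ebf2 and Lhx5, with none at Olig3. The oligodendrocyte lineage had 13 of 19 (exact test, adjusted p = 1): Olig1 (114 and 87), Sox8 (120 and 81), Olig2 (117 and 76) and Cldn11 were the highest, and Mag, Mobp and Mog had none in either replicate. Other myelin genes of the list, Mbp (98 and 75) and Cnp (99 and 73), had promoter peaks in both replicates, and Sox10 in replicate 1 only; these 3 were chosen after their values were seen. Brainstem nuclei had 14 of 26 (exact test, adjusted p = 0.253), with Egr2, a gene of hindbrain segmentation (best rank of the list), the serotonin synthesis gene Tph2 (116 and 89) and Pou4f1, and none at Chat, Dbh, Gata3 or Lmx1b. Forebrain genes had 11 of 23 (exact test, adjusted p = 0.106), among them Bcl11b, Neurod2, Lhx2 and Neurod6, with none at Fezf2, Gsx2 or Nkx2-1. Choroid plexus and ependyma had 13 of 15 (0.137), with the ciliated cell genes Ccno (138 and 125), Foxj1 and Rsph1 and the gene Enpp2, and none at Ttr or Kcne2. Neural crest and Schwann cell genes had 10 of 14 (0.853), with Prx, Egr2 and Ets1, and none at Cdh19; meningeal and fibroblast genes had 9 of 15 (0.675), with Tbx18, Col1a1, Foxc2 and Foxc1, and none at Lum or Twist1. All of these p-values are from two-sided Fisher's exact tests. Against CpG-matched lists the brainstem and forebrain lists were lower, each with an adjusted permutation p of 0.00125; the brainstem list was also lower among the stronger peaks (34.6%, adjusted p = 0.0104), and the forebrain list with only the 5′ end of each gene (34.8%, 0.0351) and without the receptor and keratin-associated families (0.0296), while in replicate 1 alone forebrain promoters reached 78.3%.

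Hox genes encode the transcription factors that set position along the head-to-tail axis, and in the hindbrain mainly the low-numbered paralogue groups are expressed. Of the 23 genes of groups 1 to 8, 15 had a promoter peak in both replicates, with high ranks at Hoxa7 (115 and 92), Hoxb5 (110 and 90) and Hoxa4 (117 and 85). Of the 16 genes of groups 9 to 13, 2 did, Hoxc10 (78 and 41) and Hoxc13 (52 and 36). In groups 1 to 8 replicate 1 alone had peaks at 21 promoters and replicate 2 at 15; Hoxb6, Hoxb7, Hoxb8, Hoxc8, Hoxd1 and Hoxd8 had one in replicate 1 only, and Hoxa3 and Hoxc6 in neither. By cluster, both replicates had promoter peaks at 6 of 11 Hoxa genes on chromosome 6, 5 of 10 Hoxb genes (chromosome 11, 96194316 to 96368256), 4 of 9 Hoxc genes (chromosome 15, 102921103 to 103036852) and 2 of 9 Hoxd genes (chromosome 2, 74668310 to 74765142). Groups 9 to 13 were lower than other genes (adjusted p = 0.000172, two-sided Fisher's exact test) and groups 1 to 8 were not told apart from them (adjusted p = 1). Hox genes lie in 4 clusters and are not independent, which the p does not allow for; the contrast between the 2 sets of groups was not itself tested. Against CpG-matched lists groups 1 to 8 were lower too, at 65.2% against 84.1% (adjusted permutation p = 0.0300).

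**Figure D3:**
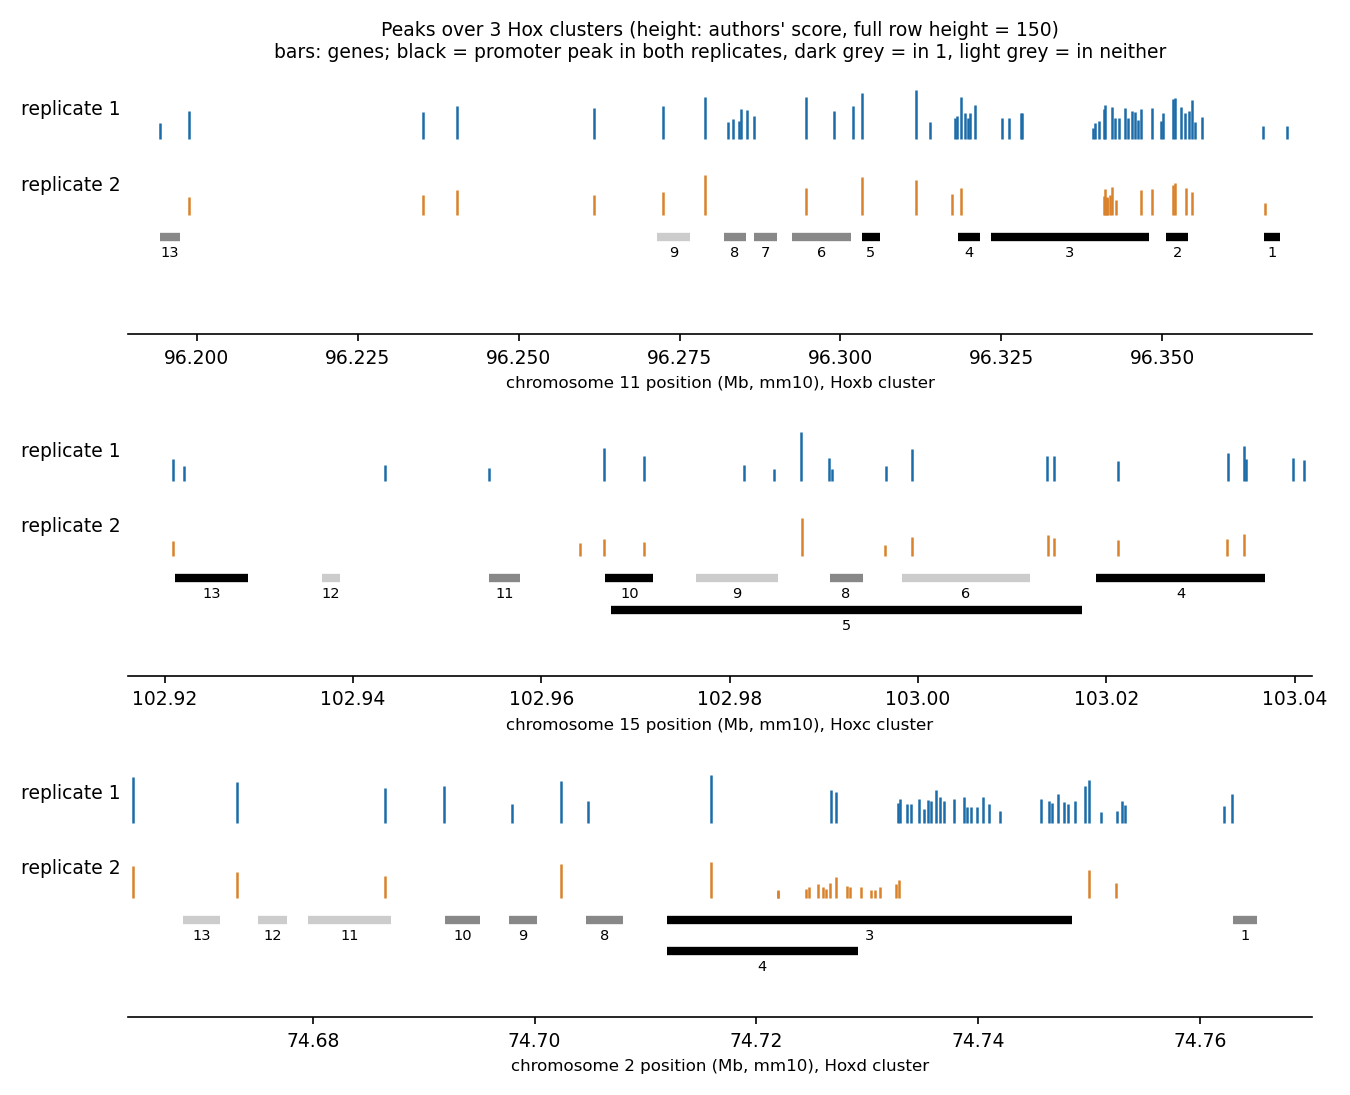
Peaks of replicate 1 (blue) and replicate 2 (orange) along the Hoxb, Hoxc and Hoxd clusters (horizontal axis, position in Mb, mm10), with line height giving the authors' score and a full row standing for 150. Bars are genes labelled by paralogue group, black with a promoter peak in both replicates, dark grey in 1 and light grey in neither; replicate 1 has 56, 18 and 43 peaks in Hoxb, Hoxc and Hoxd and replicate 2 has 25, 11 and 23.

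Regions away from promoters were then assigned to the nearest protein-coding start site. Of the shared regions 107430 (78.6%) were distal, and a gene had 4.90 of them on average with a median of 2. The oligodendrocyte, pan-neuronal, axon guidance, radial glia and astrocyte, and granule cell lists had about 2 times as many as random genes with territories of similar length. Oligodendrocyte lineage genes had 8.58 distal regions per gene, 2.20 times the matched mean, with 24 nearest Mbp, which encodes myelin basic protein, and 24 nearest Bcas1. Pan-neuronal genes had 24.1 (ratio 2.10), with 81 nearest Myt1l, a factor that holds neuronal identity, and axon guidance genes had 28.7 (1.99), with 66 nearest Robo1, the Slit receptor gene. Radial glia and astrocyte genes had 23.1 (1.99), with 80 nearest Sox9, and granule cell genes 21.6 (1.88), with 85 nearest Meis1, a cofactor of Hox proteins.

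These 5 lists had an adjusted permutation p from 0.00250 to 0.00500, from 10000 random lists matched on territory decile, two-sided with Benjamini-Hochberg adjustment over 25 lists; the unadjusted p of the oligodendrocyte and axon guidance lists, 0.0002, is the smallest that this test can give. Each replicate alone gave ratios between 1.84 and 2.08 for them. The other 20 lists were not past the threshold: the highest ratios among them were cell cycle 1.84 (adjusted permutation p = 0.151), inhibitory interneurons 1.64 (0.144), microglia 1.61 (0.229), housekeeping 1.55, skeletal muscle 1.52, Sonic hedgehog 1.39, lymphoid 1.38, Purkinje cells 1.37 and heart 1.21. Near 1 lay Hox groups 1 to 8 (1.13), erythroid (1.12), choroid plexus and ependyma (1.06), endothelial (1.03), neural crest (1.01) and brainstem nuclei (0.989), and below it liver (0.937), synapse (0.893), forebrain (0.893), meningeal and fibroblast (0.587) and Hox groups 9 to 13 (0.455). When regions in the gene body or within 50000 bp were counted in place of the nearest start site, none of the 5 lists passed (ratios 1.98 for granule cells, 1.86 pan-neuronal, 1.88 glia, 1.56 oligodendrocytes and 1.63 axon guidance, adjusted permutation p 0.0607 to 0.0737) and the inhibitory interneuron list did (1.88, 0.0300). Hox groups 1 to 8 passed in replicate 1 alone (2.10, adjusted permutation p = 0.0130), and housekeeping genes with only the 5′ end of each gene (1.90, 0.0408).

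**Figure D4:**
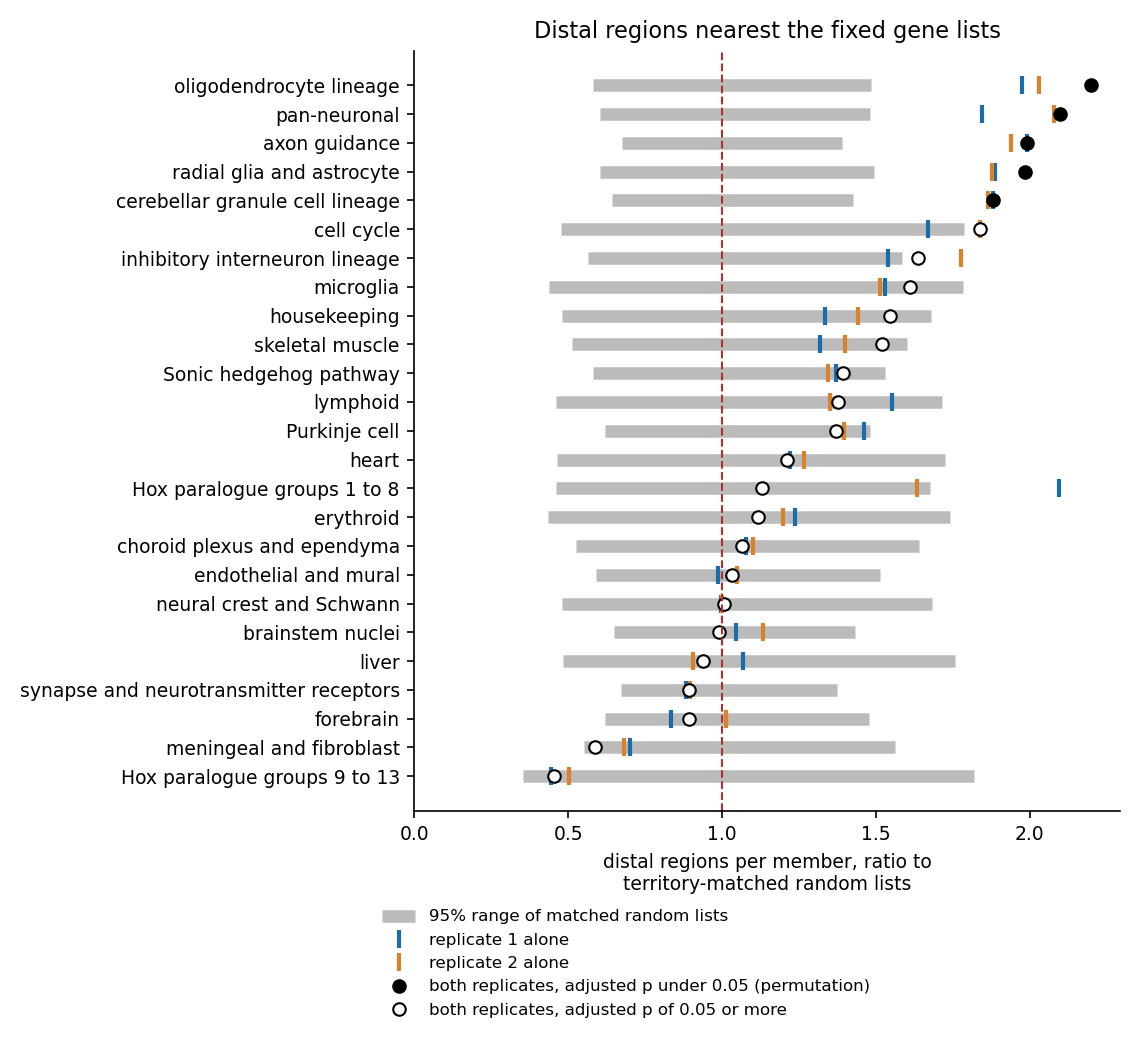
Distal regions per gene of each list, as a ratio to random lists matched on territory length (horizontal axis; 1 is the matched mean). Circles are regions found in both replicates, filled at an adjusted permutation p under 0.05, grey bars span 95% of the random lists, and blue and orange ticks are replicates 1 and 2 alone; the 5 filled circles lie between 1.88 and 2.20.

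Among single genes, Zfp608 had 150 and Auts2, linked to autism and intellectual disability, had 147, in nearest-start territories of 1283 kb and 1939 kb. They were followed by the neuronal splicing regulator gene Rbfox1 (107), the adhesion gene Lsamp (95), Gse1 (92), Lrrn3 (92), Tenm3 (92), the transcription factor gene Mef2c (91), the cadherin gene Cdh13 (89) and the phosphodiesterase gene Pde4d (86). Gse1 reached its number in a territory of 376 kb, the shortest of these 10. All 10 had a promoter peak in both replicates, and 6867 protein-coding genes (31.3%) had no distal region. A large territory holds more regions by chance, and no test was run on single genes.

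The last question was which transcription factor motifs marked the distal regions. Matches to CTCF, the insulator protein that anchors chromatin loops, were found in 5.73% of 102666 regions against 0.0448% of flanking windows, a ratio of 128, and 65.0 in replicate 1 alone. The X-box of RFX factors, regulators of ciliary genes, gave 0.208% against 0.00195% (107), a ratio that rests on very few flank matches and was 65.2 and 56.8 in replicates 1 and 2 alone. The full palindrome of nuclear factor I, the family of Nfia and Nfix, gave 0.241% against 0.00974% (24.7), and 82.3 against GC-matched windows, of which 0.00292% matched. Both of these ratios also rest on very few control matches. Its single-arm site was the most widespread, in 43.9% of regions against 20.8% of flanks (2.11). E-boxes bound by proneural factors were enriched in the forms CAGCTG (6.66% against 2.09%, ratio 3.19) and CAGATG (10.2% against 4.85%, 2.11). So was the motif of the ZIC factors of granule cells (3.28% against 1.45%, 2.27).

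Other motifs above their flanks were NRF1 (ratio 5.53), CREB (3.39), YY1 (3.17), EBF (2.47), SP/KLF (2.09), MEF2 (1.76), LHX-like (1.69), MEIS (1.68), the left arm of the REST site (1.64), ETS (1.53), the POU octamer (1.47), ROR (1.29) and AP-1 (1.21). The GATA motif was the only one past the threshold below the flanks, with 0.891% against 1.69% (0.528). In all, 21 of 34 motifs passed, 20 higher and 1 lower, by an exact binomial test on regions where only the region or only its flank matched, with Benjamini-Hochberg adjustment and a ratio beyond 1.2 in either direction in each replicate's own list. The largest adjusted p among them was 0.0199 (exact binomial test), for YY1, whose ratios rest on few matches (0.0185% of regions against 0.00584% of flanks). Motifs not past the threshold included TAATTA (1.19), SOX (1.16), GLI (1.15), HOX-PBX (1.11), PU.1 (1.11), NFY (1.088), SRF (0.977), TEAD (0.9696), RUNX (0.966), FOXA-like (0.952), HNF4 (0.828) and HNF1 (0.429). A match shows that a sequence is present and not which protein binds it, and family members share motifs. Against windows of matched GC content the REST arm (1.16) was not called, TAATTA (2.52), HOX-PBX (2.15) and FOXA-like (1.41) were higher and NFY (0.755) was lower. Of the motifs still called there, MEF2 (3.91) and LHX-like (2.65) rose and CREB (1.89) and SP/KLF (1.29) fell by over 1.5 times. AP-1 and ROR were not called among the stronger peaks (1.05 and 1.089), nor AP-1 with flanks 2000 bp away (1.21, where the ratio of at least 1 replicate did not pass), nor YY1 in replicate 2 alone (2.25, exact test, adjusted p = 0.0885), while YY1 had 5 in replicate 1 alone and 5.33 among the stronger peaks. GLI was called with flanks 2000 bp away (1.34), SOX (1.21), HNF4 (0.826) and HNF1 (0.364) in replicate 2 alone, and TAATTA (1.21), HOX-PBX (1.21) and PU.1 (1.26) in replicate 1 alone.

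**Figure D5:**
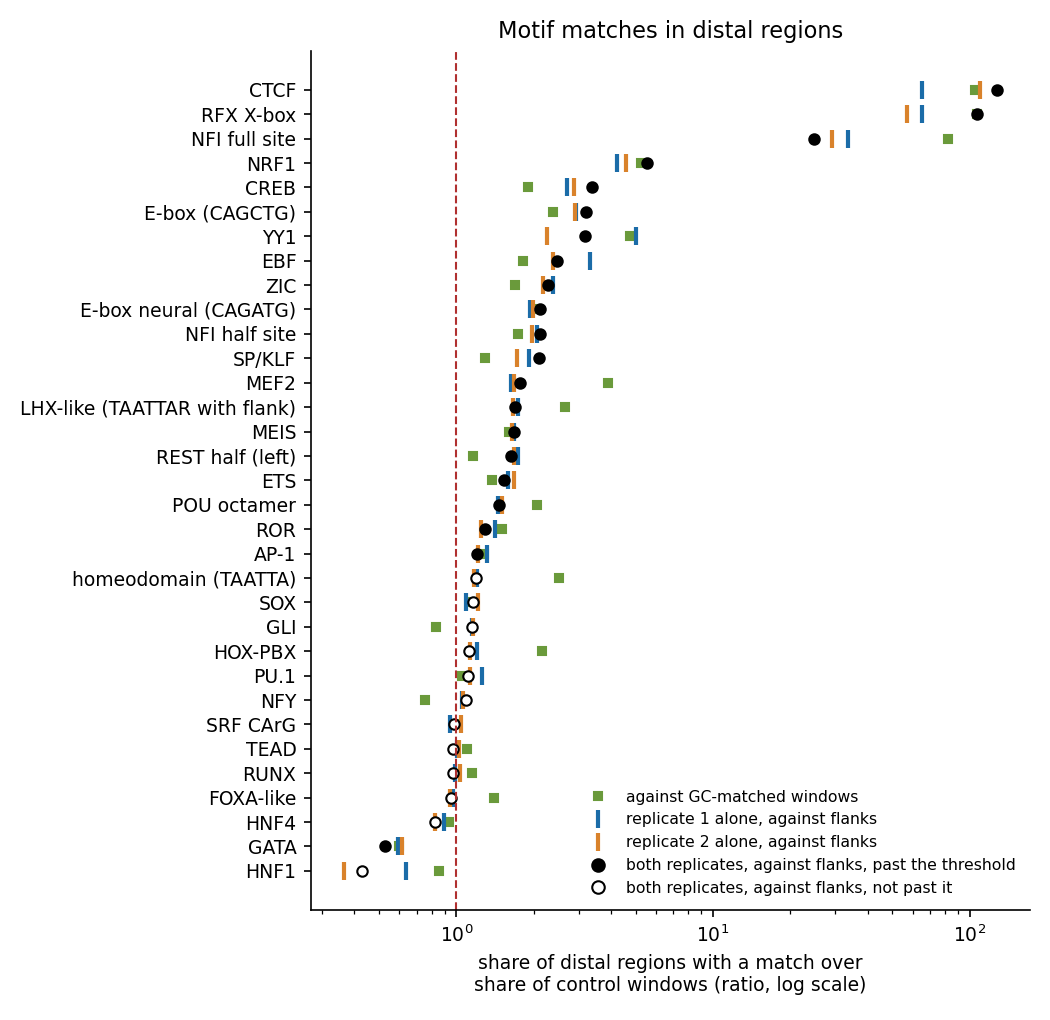
Share of distal regions with a motif match over the share of control windows (ratio, logarithmic horizontal axis). Circles are regions found in both replicates against flanks 1000 bp away, filled when past the threshold, ticks are each replicate alone and green squares are the comparison with GC-matched windows; CTCF lies highest at 128, and GATA is the only filled circle below 1, at 0.528.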

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

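The values here come from parts of the peak lists that no comparison used, and no test was chosen for them. Peaks were also called on the mitochondrial chromosome, 30 in replicate 1 and 25 in replicate 2, with median scores of 149.5 and 150 against 45 and 38 for the chromosomes that were compared. On unplaced scaffolds there were 363 peaks in replicate 1 and 187 in replicate 2, each with a median score of 31. They stand here because they are signal outside the main measurement. No explanation, technical or biological, was tested for them.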

How the results depend on the processing

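Alternatives added after the results were seen are the distal lists without their top member, neighbouring members counted once, and promoter lists without receptor families. Recovery of replicate 1 in 2 and of 2 in 1 was 60.9% and 93.4% among the stronger peaks, 47.4% and 75.2% at a reciprocal overlap of 50%, 52.7% and 86.7% with hotspots, and 70.97% and 72.2% with lists of equal length. Spearman's rho was 0.888, 0.683 and 0.902 in the first, the third and the last of these; hotspot ranks tie at the cap. The stronger peaks gave 81885 shared regions, by construction fewer. The share of regions at promoters was 29.3% among them, 27.2% with windows of 1000 bp, 15.6% with only the 5′ end, and 16.0 to 20.4% with each replicate left out. Genes with a promoter peak were 62.2%, 60.7% with only the 5′ end, and 66.8 to 70.8% with each replicate left out. CpG matching left 9 promoter lists past the threshold, 6 of them among the 17 of the main test, and counting by gene body and 50000 bp left 1 distal list, none of the 5; the cause was not tested for the distal lists. The endothelial list ranged from 38.9% to 72.2% with each replicate left out and turned to higher without replicate 2 (adjusted p = 1, Fisher's exact test), and against GC-matched windows NFY turned to a ratio of 0.755 and FOXA-like to 1.41; the cause was not tested. All 5 distal lists remained without their top member and with neighbours counted once. The direction and side of the threshold held in 185 of 225 values of single promoter lists, 216 of 250 of distal lists and 145 of 170 of motifs, and counts and levels stayed close in 37 of 58. Unknown depth limits what a missing peak means.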

Other observations

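Here the widest hotspots, the gene classes, the scan for windows and runs of peaks found in only 1 replicate, the left-out genes, and the tests of CpG content and score near the Hox and brainstem lists were chosen after results were seen; the other tests were not. The tests of CpG content and score were first set for both lists jointly and were split by list, with other bounds, after their values were seen. The widest region made by merging overlapping hotspots of both replicates, 8271 bp, spanned chromosome 13, 83734675 to 83742945 (mm10), 85922 bp from the nearest start site of Mef2c, and the next in order of width were 8062 bp at Tnrc18, 7298 bp at Zic2, 7049 bp near Tmem161b and 6833 bp at Zfp532. Promoter peaks in both replicates were found at 24.3% of lincRNA genes, 38.8% of antisense genes, 14.4% of miRNA genes and 2.79% of processed pseudogenes, against 66.3% of protein-coding genes. The X chromosome had 18.3 shared regions per Mb and the autosomes 54.2, with 5.54 and 8.45 protein-coding genes per Mb; the Y had 0.349.

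Some loci held runs of peaks in 1 replicate and none in the other, and whether they share a kind of gene was not tested. Runs of at least 8 consecutive peaks lacking a partner, with gaps of at most 2000 bp, numbered 16 in replicate 2, against a mean of 0.895 and a highest of 4 in 200 shuffles within score deciles. The longest had 19 peaks each, at Tbx20 (chromosome 9, 24767916 to 24774125, mm10) and Lhx1 (chromosome 11, 84514236 to 84522265), where replicate 1 had 0 peaks. The longest run in shuffles had 16 peaks. Others lay nearest Zfhx4 and Nfe2l3 (12 peaks each) and Zeb2 and Twist1 (11 each), lengths that shuffles also reached. Replicate 1 had 95 such runs, against a highest of 47 in shuffles, among them 32 peaks near Zfp978, 20 near Vmn1r2, 18 near Zic4 (chromosome 9, 91366376 to 91375645), 18 near Btbd35f25 and 17 near Hoxd3 (chromosome 2, 74733556 to 74742045), with 0 peaks of replicate 2. Median scores near Zfp978, Vmn1r2 and Btbd35f25 were 24.5, 14 and 8, within the range of the lowest score decile of replicate 1 (1 to 25). Near Zic4 and Hoxd3 they were 53.5 and 51. The longest run of replicate 1, 33 peaks near Ebf3, was not beyond the longest of 44 in shuffles. For replicate 1 only the number of runs, and no single run, was therefore beyond the shuffles. In windows of 200000 bp, 27 of 8566 in replicate 1 and 6 of 6385 in replicate 2 had more such peaks than any shuffle: in replicate 1 a window with Cacna1a, Ier2, Trmt1, Nacc1, Lyl1, Nfix and G430095P16Rik (61 of 93 peaks), that with Pou5f2 and Nr2f1 (43 of 48) and that of the Hoxb cluster (39 of 57) were the highest, and in replicate 2 among others that at Zfhx4 (20 of 35). The peaks in these windows had a median GC content of 55.3% in replicate 1 and 47.3% in replicate 2, against 50.7% over the whole scan of each. All of these loci were named after their values were seen.

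Replicate 1 had more peaks than replicate 2, and 3 explanations were tested. Weaker sites passing the threshold in the longer list may account for part of the excess: 97.3% of the top score decile of replicate 1 was found in replicate 2, and peaks unique to replicate 1 had a median score percentile of 28.5. Replicate 2, the shorter list, gave 99.3% and 18.0, so these values do not say how much of the excess is accounted for. With lists of equal length, recovery was still only 70.97% of replicate 1 and 72.2% of replicate 2. GC content differed between the weak distal peaks unique to each library, with medians of 48.0% in replicate 1 and 44.7% in replicate 2, a difference of 3.33 percentage points, but shared weak peaks had 46.7% in replicate 1 and 48.0% in replicate 2, so most of the gap lies in the peaks unique to replicate 2 and how far GC content bears on the excess of replicate 1 stays open. A different makeup of the tissue pieces cannot be told apart from these: 0 lists had a missing share of replicate 1 peaks past the threshold, which had been set beforehand as evidence against it, but that bound was wrong because a missed threshold limits nothing (Hox groups 1 to 8 were at 71.6% against 47.1% in matched lists, unadjusted permutation p = 0.00760, adjusted 0.190). In replicate 2 there were 2 lists past it, with adjustment over the lists of that replicate only. Depth is unknown, and apart from the makeup of the tissue pieces no biological explanation was tested, since the series has 1 group.

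Distal peaks of replicate 2 were missing from replicate 1 more often near Hox groups 1 to 8 (24 of 51, 47.1% against 17.2% in matched lists) and brainstem genes (95 of 317, 30.0% against 18.5%, adjusted permutation p = 0.0325 for each). The adjustment was over the 25 lists of each replicate separately. One over the lists of both replicates together was not made and would be stricter, so these 2 calls are weak (unadjusted permutation p = 0.0026 for each). The meningeal and fibroblast list (30.1% against 19.2%, adjusted permutation p = 0.0712) and the forebrain list (28.9% against 18.9%, 0.0550) had shares close to the brainstem list and missed the threshold. The pattern is therefore not shown to be particular to the lists that passed. The brainstem call rests on Tbx20, with 21 of 23 missing, since without it the share was 25.2% (unadjusted permutation p = 0.0562). Without the Hox member that had the most missing peaks, 13 of 37 were missing (35.1% against 17.2%, unadjusted permutation p = 0.0658), so the Hox call also rests on 1 gene. Peaks of the same open region placed apart are argued against: 17.6% (exact binomial 95% interval 11.3 to 25.7) of the 119 missing peaks lay in a hotspot of replicate 1, against 25.9% for all genes. Near the Hox list the missing share was 2.61 times that of CpG-matched lists (adjusted permutation p = 0.00500) and 2.84 times that set by peak scores (24 missing, highest of 1000 shuffles 19), which tells against CpG content and low scores as the whole cause there. Near the brainstem list neither can be told apart, at 1.68 times (adjusted permutation p = 0.0875) and 1.48 times (95 missing, highest shuffle 84), because the first misses the threshold and the second lies between the bounds. A difference in dissection could leave such loci in 1 piece only, which is a hypothesis that was not tested, and Hox genes lie in 4 clusters, so their peaks are not independent.

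Gene lists stood apart at promoters, and promoter CpG content may account for part of it. Of the 17 lists past the threshold by Fisher's exact test, 6 were still past it against CpG-matched random lists: granule cell, pan-neuronal, radial glia and astrocyte, synapse, Hox groups 9 to 13 and liver. These 6 stood apart from lists of similar CpG content at the 5′ end of the gene, the only place where it was measured. CpG content at other start sites, where a peak also counts, was not matched, so it cannot be excluded as the cause. With only the 5′ end, the glial and synapse lists did not pass Fisher's exact test. Matching also put Hox groups 1 to 8, brainstem and forebrain lists below their matched lists. CpG content goes with how widely a gene is used, so matching on it can also remove real differences, and this was not tested.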
